A study of Arabidopsis thaliana with 29 samples.

How the data were processed

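Gene expression was measured by RNA sequencing (Illumina TruSeq libraries from total RNA) in whole plants of Arabidopsis thaliana, Col-0 and pp7l. Water was withheld from soil-grown plants for 0, 6, 9, 12 or 15 days. Each of the 10 groups had 3 libraries, except Col0 at 6 D with 2, and the columns of all 29 libraries were matched to a sample by genotype, day and replicate number. The labels do not say whether replicates are separate plants or pots. The labels of the samples and of the series name different alleles of pp7l, so the mutant is written pp7l throughout.

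The authors trimmed the reads with Trimmomatic, checked them with FastQC and quantified them with Salmon against a TAIR10-based set, and deposited TPM values per gene for nuclear, plastid and mitochondrial loci, rRNA loci included. Versions of these tools are not stated. Counts are not part of the table, so depth per library and the counting error it gives are not known, and tests rest on the spread between replicates. Each library was checked to have the same total, and 0 pairs of libraries were identical. Gene names and types came from a reference annotation of a later release of the same genome, in which 32954 of 33681 loci were found. The 727 others include all 114 plastid and 122 mitochondrial loci, which were recognised by their identifiers. No coordinates were used.

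Tests used limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8) on log2(TPM + 1), without further scaling, for 18757 loci with a TPM of at least 1 in at least 3 libraries. A single model of 10 group means was fitted to all 29 libraries (19 residual degrees of freedom), with variances moderated along an intensity trend. Contrasts compared each later day with 0 D in each genotype, pp7l with Col0 at each day, and the change of pp7l with that of Col0 from 0 D to each day. Moderated F-tests joined the days. P-values were adjusted by Benjamini-Hochberg within each comparison at 0.05, and the subset changed at least 2-fold is given beside each count. Because TPM are shares of a total, every count was also computed after median-of-ratios scaling of the TPM.

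The 34 lists of genes were tested with camera in limma at a preset correlation of 0.01, with adjustment over the lists in each comparison, and again with an estimated correlation. Members were called over all genes and, separately, adjusted over the list alone. Members whose symbol the reference gives to another locus were left out, and lists of plastid and mitochondrial genes by function were not used here, because the reference does not name those loci. Shares of TPM of plastid and mitochondrial loci were compared by two-sided permutation tests, over days within a genotype and between genotypes within days, with 100000 resamples in each of 6 tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

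Groups, comparisons, their tests, gene lists, alternatives and the rule for naming genes were set before the data were examined, apart from 1 alternative and some tests of explanations that are named where they are reported. The rule named the largest changes in each direction (5 for 15 D versus 0 D and for pp7l versus Col0 at 0 D and 15 D, otherwise 2). It took them from called genes with a mean of at least 10 TPM in a compared group and no overlap between the groups, which chance gives in 10% of genes for 3 against 3. For differences in change, overlap was not considered. PP7L and members of the lists could also be named, and which members and lists appear in the text was chosen after their values were seen. The method was tested on simulated data, with 200 of 18757 genes changed, equally up and down. Each gene had its mean and pooled SD from these data, the same in all groups, with independent normal noise. In Col0 15 D versus 0 D the method recovered 53% of genes changed by 1 on the log2 scale and 94% of those changed by 2, with 10 false calls. In pp7l versus Col0 at 0 D it recovered 49% and 96%, with 8. The simulation held no shift of the total, no one-sided change and no unequal spread of groups. It therefore does not give the error rate of the real comparisons.

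Alternatives changed the pseudocount, the filter, the scaling, the loci in the total, the weights and the samples in the fit, added the replicate number as a block, and left out each library in turn. The need for a block was checked from 37 pairs of libraries with the same number. After removal of group means, 4 of the pairs correlated by more than 0.1 across genes, in a range of -0.11 to 0.26, and pp7l versus Col0 at 15 D was the only 1 of 13 comparisons in which all pairs did. The shares of protein-coding organellar loci alone were not computed for the same lack of names.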

Results

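RNA sequencing measured transcript abundance in whole plants of Arabidopsis thaliana. The accession Col-0, written Col0 here, was compared with the mutant pp7l, named for a gene of a nuclear phosphatase-like protein needed for chloroplast development. Plants grown in soil under long days went without water for 0, 6, 9, 12 or 15 days (0 D to 15 D). Each of the 10 groups holds 3 libraries, except Col0 at 6 D, which holds 2 (replicates 1 and 3), so that 14 libraries come from Col0 and 15 from pp7l. The labels name no watered plants at the later days, and a change from 0 D therefore holds both the lack of water and 6 to 15 days of age. The values are transcript abundances in TPM for 33681 loci. Read numbers are not given, so the depth is unknown. Between 17976 loci (Col0 6 D replicate 1) and 22769 loci (Col0 12 D replicate 3) were above 0 in a library, and 18757 loci were tested. Log2 changes of genes are given as fitted by limma with their standard error, and a value called relative has the change of the median gene subtracted.

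PP7L (AT5G10900) was close to the floor in every group. It stood at 0.200 ± 0.0996 TPM in Col0 and 0.586 ± 0.184 TPM in pp7l at 0 D (SD, n = 3), and its highest group mean was 1.58 ± 0.950 TPM in pp7l at 9 D (SD, n = 3). Its level was not lower in the libraries labelled pp7l, so it does not check their genotype or the allele.

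Some libraries stood apart from their groups. Col0 6 D replicate 1 had a rank correlation across genes of 0.738 with its group mate, while no pair within the other groups was below 0.928; genes are not independent replicates. Col0 6 D replicate 3 correlated at 0.938 with a library of Col0 at 9 D. Nuclear rRNA loci held 61.2% of TPM in Col0 15 D replicate 3, 27.5% in replicate 1 and 0.110% in replicate 2, and 25.0% in Col0 12 D replicate 3. The noncoding locus AT1G15405 held 46.0% of TPM in Col0 15 D replicate 2.

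The title of the series asks about organellar transcripts. Plastid loci held 72.7 ± 2.08% of TPM in Col0 at 0 D and 69.8 ± 0.846% in pp7l (SD, n = 3). In Col0 their share was 76.9 ± 13.9% at 6 D (SD, n = 2), 61.9 ± 1.18% at 9 D, 43.8 ± 11.5% at 12 D and 28.7 ± 13.2% at 15 D (SD, n = 3). In pp7l it was 69.1 ± 0.405% at 6 D, 67.9 ± 0.397% at 9 D, 65.0 ± 0.416% at 12 D and 62.1 ± 1.69% at 15 D (SD, n = 3). Permutation tests of the days gave p = 0.00087 in Col0 (adjusted 0.00174 over 6 tests) and p = 1e-05 in pp7l (adjusted 6e-05), the smallest that 100000 resamples can give. Across all days the share was 9.96 points higher in pp7l (permutation p = 0.0143, adjusted 0.0214), and without Col0 6 D replicate 3 that p was 0.0721. That difference is an average over days, since the mean share was lower in pp7l at 0 D and 6 D and higher from 9 D on. In the Col0 libraries of 12 D and 15 D in which rRNA loci held at most 0.110% of TPM, the plastid share was 54.3% and 45.6% in replicates 1 and 2 of 12 D, and 34.3% in replicate 2 of 15 D, where AT1G15405 held 46.0%.

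Mitochondrial loci held 0.716 ± 0.00589% of TPM in Col0 and 0.837 ± 0.0344% in pp7l at 0 D (SD, n = 3). Their share was 1.95 ± 0.376% at 12 D and 1.22 ± 0.661% at 15 D in Col0, and 1.48 ± 0.0988% and 1.76 ± 0.00617% in pp7l (SD, n = 3). The days differed in Col0 (permutation p = 0.0242, adjusted 0.029) and in pp7l (permutation p = 2e-05, adjusted 6e-05). In Col0 that p was 0.0558 to 0.0585 without any 1 of the 0 D libraries, or without replicate 1 or 2 of 12 D. Across all days the difference of -0.0484 points between pp7l and Col0 did not pass (permutation p = 0.701).

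**Figure D1:**
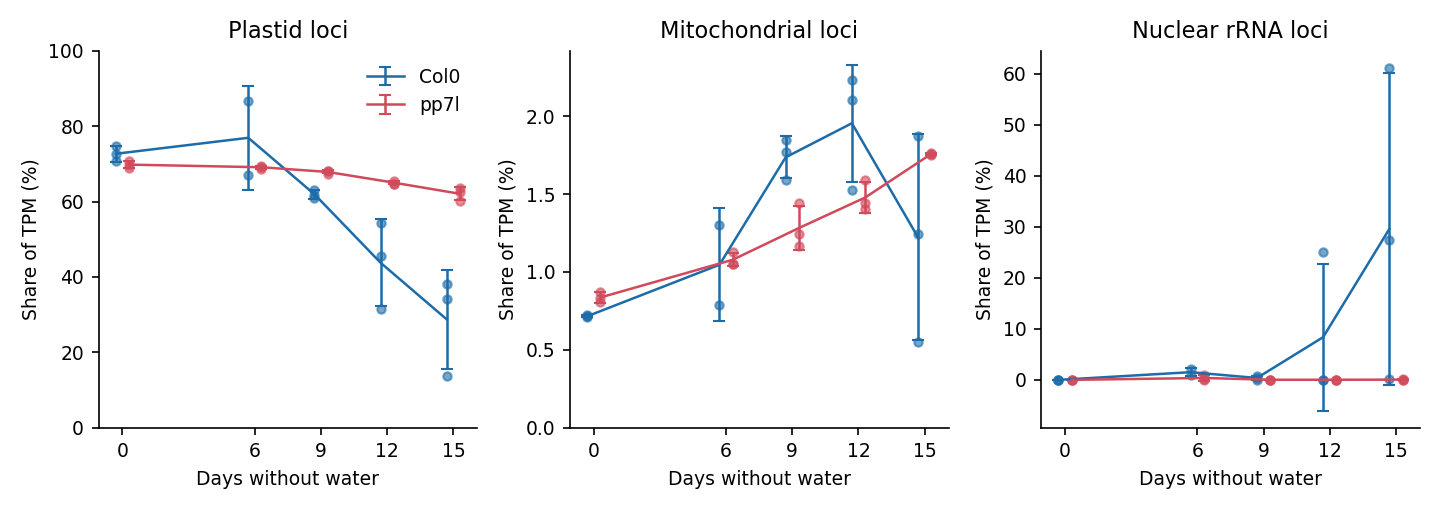
Share of TPM (%) held by plastid, mitochondrial and nuclear rRNA loci against days without water in Col0 (blue) and pp7l (red); points are libraries, lines join group means and bars are SD. At 15 D the plastid share was 62.1% in pp7l and 28.7% in Col0, where rRNA loci (up to 61.2% in 1 library) and AT1G15405 lower it.

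The changes in Col0 after 6 D show the first stage without water, on only 2 libraries that differed strongly from each other. A gene of photosystem II was lower and nuclear rRNA loci were higher. PSBTN (AT3G21055), a subunit of photosystem II, went from 1038 ± 38.2 TPM (SD, n = 3) to 179 ± 252 TPM (SD, n = 2), a log2 change of -5.31 ± 0.99 (SE), or -5.44 relative (adjusted p = 3.98e-04). AT5G08760 changed by -4.23 ± 0.57 (SE), or -4.36 relative (adjusted p = 1.28e-05). Without Col0 6 D replicate 1 these changes were -1.53 and -2.36, and without replicate 3 -9.08 and -6.10. The rRNA loci AT3G41979 and AT3G41768 changed by 6.58 and 6.56 relative (adjusted p = 1.52e-04 and 0.00805).

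For Col0 6 D versus 0 D limma called 4754 of 18757 genes, 3003 higher and 1751 lower, with 1615 and 1467 of them changed at least 2-fold; the median gene changed by 0.13. After median-of-ratios scaling, 4742 were higher and 5307 lower. The count was 8193 without Col0 6 D replicate 1 and 8117 without Col0 6 D replicate 3, where the lone Col0 6 D library is assumed to vary like the other groups. A limma fit on these 5 libraries alone called 0 genes (2602 at an unadjusted p under 0.05) and none of the genes named here passed in it. With limma's array weights 2 genes were called, 2 lower and 0 higher, so the rRNA loci lost their call there.

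After 9 D Col0 had more transcripts of lipid transfer, wax, anthocyanin and floral genes, and less of the light-harvesting genes. LTP4 (AT5G59310) and LTP3 (AT5G59320), lipid transfer proteins of the epidermis, went from 0.961 ± 0.230 to 771 ± 19.4 TPM (SD, n = 3) and from 5.63 ± 1.47 to 818 ± 105 TPM (SD, n = 3). The log2 change of LTP4 was 8.63 ± 0.43 (SE), or 7.77 relative (adjusted p = 6.10e-14) and that of LTP3 was 6.97 ± 0.56 (SE), or 6.11 relative (adjusted p = 3.13e-10). LHB1B1 (AT2G34430), a light-harvesting protein of photosystem II, changed by -5.40 ± 0.35 (SE), or -6.27 relative (adjusted p = 6.15e-12), and AT1G66100 by -6.04 ± 0.39 (SE), or -6.90 relative (adjusted p = 5.39e-12). The senescence protease gene SAG12 (AT5G45890) changed by 5.87 ± 0.47 (SE), or 5.01 relative (adjusted p = 2.87e-10).

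Of all 18757 tested genes, 12151 were called higher in Col0 at 9 D (4916 after median-of-ratios scaling), and member counts stand against that share. By group, 13 of 13 measured anthocyanin genes were higher (13 higher adjusted over the list alone). Their median was 3.08 relative (camera, adjusted p = 3.63e-09, and adjusted p = 0.324 with an estimated correlation), with DFR (AT5G42800), a dihydroflavonol reductase, at 4.65 and TT4 (AT5G13930), chalcone synthase, at 4.34 relative. Of the wax and lipid transfer genes, 9 of 9 measured genes were higher (9 higher adjusted over the list alone). Their median was 1.87 relative (camera, adjusted p = 1.15e-04, and adjusted p = 0.324 with an estimated correlation), with CER1 (AT1G02205) at 2.76 relative. Of the floral organ markers, 7 of 7 measured genes were higher (7 higher adjusted over the list alone). Their median was 1.43 relative (camera, adjusted p = 4.32e-04, and adjusted p = 0.324 with an estimated correlation). PI (AT5G20240) and SEP3 (AT1G24260), regulators of floral organ identity, stood at 2.32 and 2.2 relative. For ABA and dehydration, 20 of 24 measured marker genes were higher (21 higher and 1 lower adjusted over the list alone). Their median was 1.23 relative (camera, adjusted p = 0.0275, and adjusted p = 0.729 with an estimated correlation). That list's camera p was 0.0537 without Col0 0 D replicate 2 and 0.0896 without Col0 9 D replicate 3, in a range of 0.00298 to 0.0896 over its alternatives. RAB18 (AT5G66400), a dehydrin, stood at 2.80 and HAI2 (AT1G07430), a clade A protein phosphatase, at 2.38 relative. Among photosynthesis genes, 16 of 20 measured light-harvesting genes were lower and 1 higher (17 lower and 1 higher adjusted over the list alone). Their median was -2.16 relative (camera, adjusted p = 8.11e-26, and adjusted p = 0.324 with an estimated correlation). Of the nuclear genes of photosystems and electron transport, 14 of 26 measured genes were lower (13 lower adjusted over the list alone). Their median was -2.08 relative (camera, adjusted p = 1.04e-24, and adjusted p = 0.324 with an estimated correlation). PSAN (AT5G64040), a subunit of photosystem I, stood at -2.96 relative.

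For Col0 9 D versus 0 D limma called 12692 genes, 12151 higher and 541 lower, with 7835 and 323 changed at least 2-fold, around a median gene at 0.86. Median-of-ratios scaling gave 4916 higher and 4713 lower, and 405 genes were called in opposite directions by the scalings. The genes named for this day kept their direction and call after that scaling.

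By 12 D the dehydration and phosphatase genes of Col0 had risen and photosynthesis genes had fallen. RAB18 went from 1.68 ± 0.594 to 2715 ± 646 TPM (SD, n = 3), a log2 change of 9.98 ± 0.53 (SE), or 9.02 relative (adjusted p = 1.44e-14). HAI1 (AT5G59220), a clade A phosphatase of ABA signalling, changed by 7.25 ± 0.34 (SE), or 6.29 relative (adjusted p = 2.30e-15), ELIP1 (AT3G22840), an early light-induced protein, by 10.11 ± 0.53 (SE), or 9.14 relative (adjusted p = 1.45e-14), and LTP4 by 10.20 ± 0.43 (SE), or 9.24 relative (adjusted p = 5.53e-16). LHB1B1 went from 2257 ± 212 to 5.67 ± 0.405 TPM (SD, n = 3), and GER1 (AT1G72610), a germin-like protein, changed by -7.22 ± 0.34 (SE), or -8.19 relative (adjusted p = 2.30e-15).

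Member counts at 12 D stand against 11609 of all 18757 tested genes called higher (6579 after median-of-ratios scaling). Of the ABA and dehydration markers, 22 of 24 measured genes were higher and 1 lower (22 higher and 1 lower adjusted over the list alone). Their median was 3.83 relative (camera, adjusted p = 2.11e-05, and adjusted p = 0.428 with an estimated correlation). Of the clade A phosphatases, 9 of 9 measured genes were higher (9 higher adjusted over the list alone). Their median was 2.77 relative (camera, adjusted p = 2.54e-05, and adjusted p = 0.302 with an estimated correlation). On the falling side, 20 of 20 measured light-harvesting genes were lower (20 lower adjusted over the list alone). Their median was -5.19 relative (camera, adjusted p = 6.87e-25, and adjusted p = 0.179 with an estimated correlation). In the Calvin-Benson cycle, 15 of 17 measured genes were lower (15 lower adjusted over the list alone). Their median was -3.68 relative (camera, adjusted p = 1.24e-14, and adjusted p = 0.179 with an estimated correlation). PSAN stood at -6.77 and the Rubisco small subunit gene RBCS3B (AT5G38410) at -5.68 relative. Of the aquaporins, 13 of 17 measured genes were lower and 2 higher (13 lower and 2 higher adjusted over the list alone). Their median was -3.04 relative (camera, adjusted p = 5.08e-11, and adjusted p = 0.261 with an estimated correlation). In glucosinolate synthesis, 8 of 10 measured genes were lower (8 lower adjusted over the list alone). Their median was -3.23 relative (camera, adjusted p = 2.62e-08, and adjusted p = 0.235 with an estimated correlation). Of the floral organ markers, 7 of 7 measured genes were higher (7 higher adjusted over the list alone). Their median was 1.17 relative (camera, adjusted p = 0.119, and adjusted p = 0.701 with an estimated correlation), and the list passed in 3 of 36 alternatives (adjusted p from 0.0258 to 0.261). PI went from 0.195 ± 0.189 to 4.32 ± 0.807 TPM (SD, n = 3) and SEP3 from 0.342 ± 0.0106 to 7.73 ± 0.940 TPM (SD, n = 3). BAN and STK, genes of seed coat and ovule named after their values were seen, were listed at 0 at 0 D and stood at 5.21 ± 1.72 and 3.24 ± 0.913 TPM at 12 D (SD, n = 3). Among plastid-encoded transcripts, 41 of 71 measured plastid loci were lower and 4 higher (41 lower and 4 higher adjusted over the list alone). Their median was -2.18 relative (camera, adjusted p = 1.00e-17, and adjusted p = 0.261 with an estimated correlation), while rRNA loci held 25.0% of TPM in replicate 3.

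For Col0 12 D versus 0 D limma called 13837 genes, 11609 higher and 2228 lower (9133 and 1523 at least 2-fold), around a median gene at 0.97. With median-of-ratios scaling 6579 were higher and 6493 lower, with 548 genes called in opposite directions.

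At 15 D, the last day, Col0 had little transcript left of LHB1B1 and other photosynthesis genes and carried transcripts of seed storage proteins. LHB1B1 went from 2257 ± 212 to 0.888 ± 0.594 TPM (SD, n = 3), a log2 change of -10.27 ± 0.35 (SE), or -10.03 relative (adjusted p = 9.14e-18). CA1 (AT3G01500), a carbonic anhydrase of the chloroplast, changed by -8.92 ± 0.44 (SE), or -8.68 relative (adjusted p = 4.78e-15), and CAB3 (AT1G29910), LHCB2.3 (AT3G27690) and ECS1 (AT1G31580) by -8.72, -8.60 and -8.57 relative. Among the rises, AT1G05340 changed by 8.69 ± 0.52 (SE), or 8.92 relative (adjusted p = 2.35e-13), and ELIP1, LTP4 and the defensin gene PDF2.1 (AT2G02120) by 8.64, 8.08 and 7.53 relative. The rRNA locus AT2G01020 changed by 10.01 ± 2.62 (SE), or 10.24 relative (adjusted p = 0.0022). Nuclear rRNA loci held 0.110% to 61.2% of TPM in the Col0 15 D libraries. Whether RNA quality adds to the changes at this day was not tested.

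In seed storage, 9 of 9 measured genes were higher (9 higher adjusted over the list alone). Their median was 4.84 relative (camera, adjusted p = 1.20e-15, and adjusted p = 0.112 with an estimated correlation). SESA3 (AT4G27160), an albumin, went from 0.0741 ± 0.128 to 49.1 ± 37.3 TPM (SD, n = 3), and CRA1 (AT5G44120), a cruciferin, changed by 5.11 ± 0.33 (SE), or 5.34 relative (adjusted p = 6.42e-13). OLEO2 (AT5G40420), an oleosin, was listed at 0 in Col0 at 0 D and stood at 35.6 ± 14.7 TPM at 15 D (SD, n = 3). The median of log2(TPM + 1) over the storage genes was 4.34, 5.36 and 4.05 in the Col0 15 D libraries and 0 in every Col0 0 D library, so their fitted changes depend on the pseudocount.

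Among photosynthesis genes, 20 of 20 measured light-harvesting genes were lower (20 lower adjusted over the list alone). Their median was -7.06 relative (camera, adjusted p = 3.35e-19, and adjusted p = 0.213 with an estimated correlation). Of photosystem and electron transport genes, 26 of 26 measured genes were lower (26 lower adjusted over the list alone). Their median was -6.56 relative (camera, adjusted p = 3.35e-19, and adjusted p = 0.213 with an estimated correlation), with PSAN at -8.24 relative. In the Calvin-Benson cycle, 17 of 17 measured genes were lower (17 lower adjusted over the list alone). Their median was -5.02 relative (camera, adjusted p = 3.74e-12, and adjusted p = 0.213 with an estimated correlation), with RBCS2B (AT5G38420) at -7.90 relative. In tetrapyrrole synthesis, 16 of 16 measured genes were lower (16 lower adjusted over the list alone). Their median was -2.87 relative (camera, adjusted p = 2.30e-10, and adjusted p = 0.213 with an estimated correlation), with CHLM (AT4G25080) at -5.29 relative. Among plastid-encoded transcripts, 65 of 71 measured loci were lower and 1 higher (66 lower and 1 higher adjusted over the list alone). Their median was -3.40 relative (camera, adjusted p = 3.56e-18, and adjusted p = 0.238 with an estimated correlation), in libraries where rRNA loci held 0.110% to 61.2% of TPM. Of the aquaporins, 15 of 17 measured genes were lower (15 lower adjusted over the list alone). Their median was -3.56 relative (camera, adjusted p = 1.94e-08, and adjusted p = 0.354 with an estimated correlation), with the tonoplast channels TIP2 (AT3G26520) and DELTA-TIP (AT3G16240) at -7.47 and -6.85 relative. Of the expansins, 8 of 8 measured genes were lower (8 lower adjusted over the list alone). Their median was -2.60 relative (camera, adjusted p = 4.75e-06, and adjusted p = 0.213 with an estimated correlation). EXPA8 (AT2G40610) was listed at 0 in Col0 at 15 D after 29.7 ± 3.04 TPM at 0 D (SD, n = 3). In glucosinolate synthesis, 9 of 10 measured genes were lower (9 lower adjusted over the list alone). Their median was -2.58 relative (camera, adjusted p = 7.46e-05, and adjusted p = 0.354 with an estimated correlation), with BCAT4 (AT3G19710) at -4.76 and CYP83A1 (AT4G13770) at -4.70 relative.

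Of the ABA and dehydration markers, 16 of 24 measured genes were higher and 3 lower (16 higher and 3 lower adjusted over the list alone). Their median was 2.3 relative (camera, adjusted p = 2.28e-07, and adjusted p = 0.387 with an estimated correlation). RAB18 stood at 7.40 relative, while COR15B (AT2G42530), a cold-regulated chloroplast protein, changed by -5.55 ± 0.40 (SE), or -5.32 relative (adjusted p = 7.54e-12). Of the clade A phosphatases, 9 of 9 measured genes were higher (9 higher adjusted over the list alone). Their median was 2.78 relative (camera, adjusted p = 6.45e-10, and adjusted p = 0.213 with an estimated correlation), with HAI1 at 6.44 relative. In senescence and chlorophyll breakdown, 10 of 16 measured genes were higher and 4 lower (11 higher and 4 lower adjusted over the list alone). Their median was 1.32 relative (camera, adjusted p = 0.00135, and adjusted p = 0.463 with an estimated correlation). SAG21 (AT4G02380) and SAG12 stood at 6.59 and 3.71 relative. For Col0 15 D versus 0 D limma called 9630 genes, 3130 higher and 6500 lower (1908 and 4601 at least 2-fold), around a median gene at -0.23. After median-of-ratios scaling 7082 were higher and 6381 lower.

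**Figure D2:**
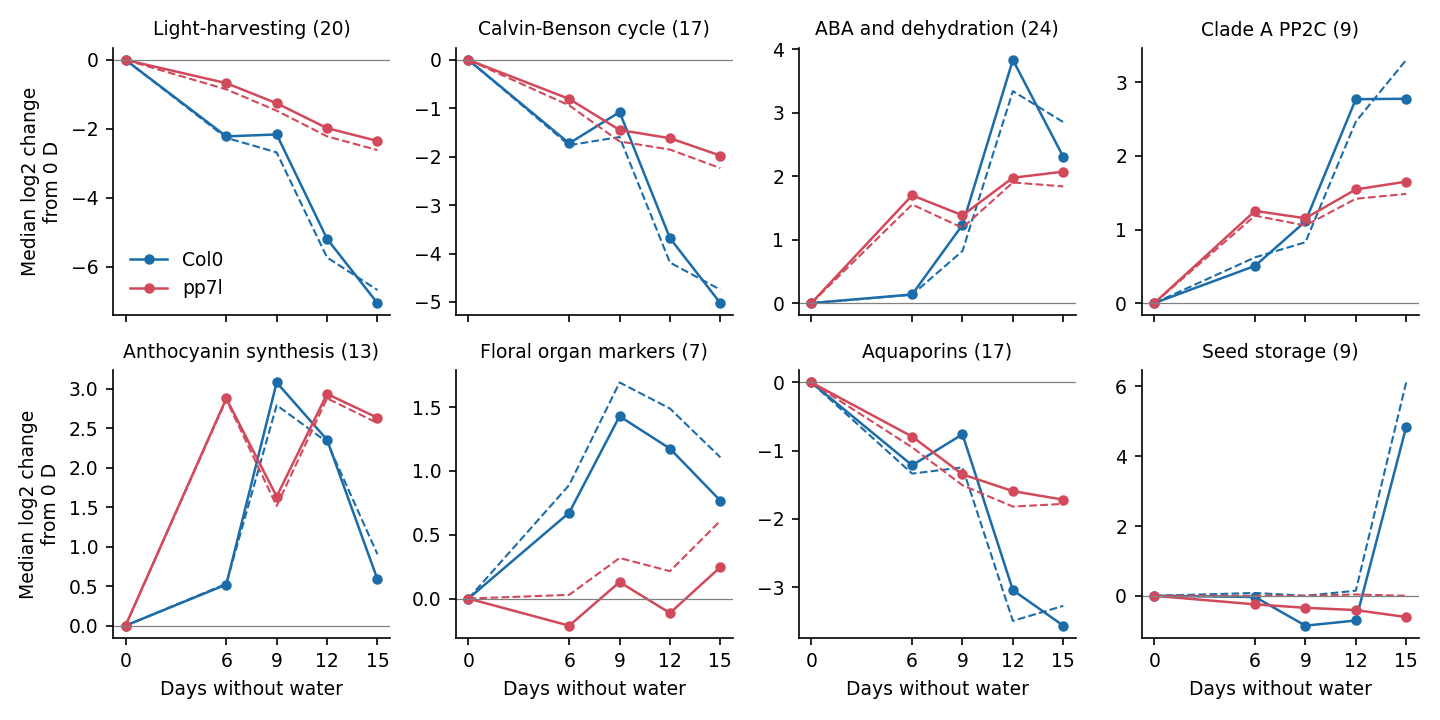
Median log2 change from 0 D of 8 gene lists (number of measured genes in brackets) against days without water in Col0 (blue) and pp7l (red). Solid lines are relative to the median gene and dashed lines follow median-of-ratios scaling; the light-harvesting median reached -7.06 in Col0 and -2.35 in pp7l at 15 D.

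At 6 D dehydration and anthocyanin transcripts were higher in pp7l than at 0 D. LTP3 went from 1.34 ± 0.304 to 224 ± 5.98 TPM (SD, n = 3), a log2 change of 6.60 ± 0.56 (SE), or 6.35 relative (adjusted p = 4.44e-09). AT3G02480 changed by 5.50 ± 0.47 (SE), or 5.26 relative (adjusted p = 4.13e-09), LEA4-5 (AT5G06760), a late embryogenesis abundant protein, by 4.45 ± 0.42 (SE), or 4.2 relative (adjusted p = 3.65e-08), and DFR by 5.27 ± 0.45 (SE), or 5.03 relative (adjusted p = 4.23e-09). GER3 (AT5G20630), a germin-like protein, changed by -3.31 ± 0.48 (SE), or -3.55 relative (adjusted p = 2.50e-05) and AT3G16670 by -3.17 ± 0.18 (SE), or -3.42 relative (adjusted p = 4.99e-12).

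In anthocyanin synthesis, 13 of 13 measured genes were higher (13 higher adjusted over the list alone). Their median was 2.88 relative (camera, adjusted p = 1.10e-18, and adjusted p = 0.147 with an estimated correlation), with LDOX (AT4G22880) at 3.97 relative. Of the ABA and dehydration markers, 20 of 24 measured genes were higher and 1 lower (21 higher and 1 lower adjusted over the list alone). Their median was 1.70 relative (camera, adjusted p = 1.69e-13, and adjusted p = 0.349 with an estimated correlation), with RAB18 at 4.02 relative. Of the clade A phosphatases, 8 of 9 measured genes were higher (8 higher adjusted over the list alone). Their median was 1.25 relative (camera, adjusted p = 6.40e-07, and adjusted p = 0.349 with an estimated correlation), with HAI1 at 2.1 relative. The storage protein gene VSP2 (AT5G24770), induced by jasmonate, stood at 4.47, FLN1 (AT3G54090), a fructokinase-like protein of the plastid transcription apparatus, at -1.74 and RBCS1B (AT5G38430) at -2.46 relative.

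For pp7l 6 D versus 0 D limma called 4010 genes, 3278 higher and 732 lower (1251 and 403 at least 2-fold), around a median gene at 0.25. After median-of-ratios scaling 2783 were higher and 3192 lower. The count was 2205 and 2330 without pp7l 0 D replicates 1 and 2. It was 2567, 2554 and 2473 without pp7l 6 D replicates 1, 2 and 3. It was 9655 in a fit on these 6 libraries, where the spread of Col0 6 D does not enter.

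At 9 D LTP3 in pp7l changed by 6.61 ± 0.56 (SE), or 6.27 relative (adjusted p = 5.90e-09), and HIS1-3 (AT2G18050), a drought-inducible linker histone, went from 1.79 ± 0.488 to 132 ± 8.94 TPM (SD, n = 3). PCR1 (AT1G14880), a metal transport protein, changed by -4.71 ± 0.60 (SE), or -5.05 relative (adjusted p = 3.31e-06) and AT3G16670 by -3.82 ± 0.18 (SE), or -4.16 relative (adjusted p = 4.63e-14). For pp7l 9 D versus 0 D limma called 6139 genes, 5190 higher and 949 lower (2064 and 572 at least 2-fold), around a median gene at 0.34, and 3982 without pp7l 9 D replicate 3. After median-of-ratios scaling 3128 were higher and 3819 lower.

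By 12 D, LTP3 in pp7l had changed by 6.97 ± 0.56 (SE), or 6.51 relative (adjusted p = 7.44e-10), and NUDT24 (AT5G19470), a nudix hydrolase, had gone from 0.0827 ± 0.0935 to 68.9 ± 14.2 TPM (SD, n = 3). LHB1B1 went from 1359.6 ± 43.7 to 53.0 ± 5.46 TPM (SD, n = 3), a log2 change of -4.66 ± 0.35 (SE), or -5.12 relative (adjusted p = 2.41e-10), and AT2G12461 was listed at 0 after 25.3 ± 1.44 TPM at 0 D (SD, n = 3). For pp7l 12 D versus 0 D limma called 8277 genes, 7094 higher and 1183 lower (3281 and 670 at least 2-fold), around a median gene at 0.46. After median-of-ratios scaling 3661 were higher and 4130 lower.

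At 15 D pp7l carried raised dehydration, phosphatase and anthocyanin transcripts and lowered photosynthesis transcripts. RAB18 went from 2.00 ± 1.01 to 149.9 ± 85.3 TPM (SD, n = 3), a log2 change of 5.48 ± 0.53 (SE), or 4.87 relative (adjusted p = 1.36e-08). LTP3 changed by 6.43 ± 0.56 (SE), or 5.82 relative (adjusted p = 3.78e-09), and ELIP1, HIS1-3, AT1G05340 and NUDT24 by 5.66, 5.52, 5.50 and 5.45 relative. LHB1B1 went from 1359.6 ± 43.7 to 33.6 ± 4.34 TPM (SD, n = 3), and AT1G66100, AT3G05730, MSRB6 (AT4G04840) and CAB2 (AT1G29920) changed by -5.14, -4.92, -4.73 and -4.67 relative.

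In pp7l at 15 D, 9255 of all 18757 tested genes were called higher (4084 after median-of-ratios scaling). Of the ABA and dehydration markers in pp7l at 15 D, 23 of 24 measured genes were higher (23 higher adjusted over the list alone). Their median was 2.07 relative (camera, adjusted p = 1.56e-09, and adjusted p = 0.247 with an estimated correlation). Of the clade A phosphatases, 8 of 9 measured genes were higher (8 higher adjusted over the list alone). Their median was 1.65 relative (camera, adjusted p = 2.68e-05, and adjusted p = 0.247 with an estimated correlation), with HAI2 at 2.90 relative. In anthocyanin synthesis, 13 of 13 measured genes were higher (13 higher adjusted over the list alone). Their median was 2.64 relative (camera, adjusted p = 1.56e-09, and adjusted p = 0.18 with an estimated correlation), with DFR at 4.16 relative. SAG12 stood at 4.01 and FMO1 (AT1G19250), a monooxygenase of systemic defence, at 4.18 relative. Among the falls, 17 of 20 measured light-harvesting genes were lower (19 lower adjusted over the list alone). Their median was -2.35 relative (camera, adjusted p = 1.28e-23, and adjusted p = 0.115 with an estimated correlation). In the Calvin-Benson cycle, 10 of 17 measured genes were lower (12 lower adjusted over the list alone). Their median was -1.98 relative (camera, adjusted p = 9.01e-16, and adjusted p = 0.115 with an estimated correlation), with RBCS3B at -4.18 relative. Of the aquaporins, 11 of 17 measured genes were lower and 1 higher (13 lower and 1 higher adjusted over the list alone). Their median was -1.72 relative (camera, adjusted p = 5.89e-14, and adjusted p = 0.18 with an estimated correlation), with DELTA-TIP at -3.14 relative. Of the expansins, 6 of 8 measured genes were lower (6 lower adjusted over the list alone). Their median was -1.42 relative (camera, adjusted p = 6.41e-08, and adjusted p = 0.115 with an estimated correlation), with EXPA8 at -2.84 relative.

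For pp7l 15 D versus 0 D limma called 10325 genes, 9255 higher and 1070 lower (4919 and 622 at least 2-fold), around a median gene at 0.61. After median-of-ratios scaling 4084 were higher and 4283 lower.

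Before drought, pp7l carried more transcripts of salicylic acid defence genes and of the nuclear-encoded plastid transcription apparatus than Col0. PR1 (AT2G14610), a pathogenesis-related protein, stood at 155 ± 7.56 TPM in pp7l and 10.8 ± 0.400 TPM in Col0 (SD, n = 3), a log2 difference of 3.73 ± 0.73 (SE), or 3.44 relative (adjusted p = 8.91e-04). BGL2 (AT3G57260), a glucanase of defence, and CHI (AT2G43570), a chitinase, differed by 2.82 and 2.59, AT1G75945 by 3.12 and the pseudogene AT4G04293 by 3.16 relative. MIR841a (AT4G13564), a microRNA locus, was listed at 0 in pp7l and stood at 29.9 ± 14.9 TPM in Col0 (SD, n = 3). CYSA (AT2G40880), a cystatin, MEE3 (AT2G21650), CML38 (AT1G76650), a calmodulin-like protein, and AT4G13575 differed by -3.13, -2.77, -2.73 and -2.85 relative.

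In the plastid transcription apparatus, 14 of 21 measured genes were higher (16 higher adjusted over the list alone). Their median was 1.02 relative (camera, adjusted p = 2.12e-09, and adjusted p = 0.509 with an estimated correlation). FLN1 stood at 8.72 ± 1.24 TPM in pp7l and 1.43 ± 0.220 TPM in Col0 (SD, n = 3), a log2 difference of 2.00 ± 0.28 (SE), or 1.72 relative (adjusted p = 1.99e-05). PDE312 (AT3G48500) and FSD3 (AT5G23310), other parts of that apparatus, differed by 1.40 and 1.60 relative. Of the organelle RNA editing factors, 12 of 25 measured genes were higher (19 higher adjusted over the list alone). Their median was 0.39 relative (camera, adjusted p = 3.56e-04, and adjusted p = 0.674 with an estimated correlation). That camera p was 0.134 with a minimum of 5 TPM, in a range of 1.10e-06 to 0.134 over its alternatives. Of the salicylic acid and defence genes, 13 of 15 measured genes were higher (13 higher adjusted over the list alone). Their median was 0.98 relative (camera, adjusted p = 1.05e-06, and adjusted p = 0.574 with an estimated correlation). GUN5 (AT5G13630), a magnesium chelatase subunit, and LOX2 (AT3G45140), a lipoxygenase of jasmonate synthesis, differed by 1.38 and 1.71 relative. On the lower side, ERD14 (AT1G76180), a dehydrin, and CBF2 (AT4G25470), a cold response regulator, differed by -1.75 and -1.68 relative. The clock gene PRR5 (AT5G24470) stood at 9.28 ± 0.863 TPM in pp7l and 0.912 ± 0.138 TPM in Col0 (SD, n = 3). GI (AT1G22770), another clock gene, stood at 9.50 ± 1.29 TPM in pp7l and 1.89 ± 0.635 TPM in Col0 (SD, n = 3). Other clock genes are not given here, and a difference in clock phase at harvest was not tested. Of the root markers, 3 of 3 measured genes were higher (3 higher adjusted over the list alone). Their median was 1.71 relative (camera, adjusted p = 1.48e-04, and adjusted p = 0.204 with an estimated correlation), and the others were too low to test. PYK10 (AT3G09260), a glucosidase of roots, stood at 26.6 ± 2.55 TPM in pp7l and 6.20 ± 2.35 TPM in Col0 (SD, n = 3), NRT2:1 (AT1G08090), a nitrate transporter, at 8.65 ± 0.405 TPM in pp7l and 0.606 ± 0.201 TPM in Col0 (SD, n = 3) and CASP1 (AT2G36100), a protein of the Casparian strip, at 0.983 ± 0.389 TPM in pp7l and 0.0305 ± 0.0529 TPM in Col0 (SD, n = 3).

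For pp7l versus Col0 at 0 D limma called 3794 genes, 3525 higher and 269 lower in pp7l (1454 and 137 at least 2-fold), around a median gene at 0.28. After median-of-ratios scaling 3201 were higher and 3397 lower. The count was 2432 and 1369 without Col0 0 D replicates 1 and 3, and 1634 without pp7l 0 D replicate 3.

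At 6 D, AT2G37870 stood at 61.7 ± 2.42 TPM in pp7l (SD, n = 3) and 2.96 ± 4.18 TPM in Col0 (SD, n = 2), a log2 difference of 4.57 ± 0.57 (SE), or 4.08 relative (adjusted p = 4.33e-06). VSP2 differed by 4.18 ± 0.51 (SE), or 3.68 relative (adjusted p = 3.15e-06). Of the floral organ markers, 5 of 7 measured genes were lower (6 lower adjusted over the list alone). Their median was -1.37 relative (camera, adjusted p = 8.58e-13, and adjusted p = 0.064 with an estimated correlation). GRP19 (AT5G07550), an oleosin-like protein of the pollen coat, was listed at 0 in pp7l and stood at 32.7 ± 39.1 TPM in Col0 (SD, n = 2). AT3G06435 differed by -4.23 ± 0.90 (SE), or -4.73 relative (adjusted p = 0.00202), but by -0.83 without Col0 6 D replicate 1 (adjusted p = 0.302, in a range of 3.90e-14 to 0.964 over its alternatives).

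For pp7l versus Col0 at 6 D limma called 5407 genes, 4857 higher and 550 lower (2876 and 365 at least 2-fold), around a median gene at 0.50. After median-of-ratios scaling 3508 were higher and 3280 lower. The count was 727 without Col0 6 D replicate 1, 13033 without Col0 6 D replicate 3, 3269 without pp7l 6 D replicate 1, 3118 without pp7l 6 D replicate 2 and 3095 without pp7l 6 D replicate 3, with a lone Col0 library assumed to vary like the other groups. It was 0 in a limma fit on these 5 libraries (2119 at an unadjusted p under 0.05) and 0 with limma's array weights (883), and none of the genes named here passed in either.

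At 9 D pp7l had less transcript of floral, wax and anthocyanin genes than Col0. PI stood at 0.623 ± 0.452 TPM in pp7l and 9.86 ± 1.75 TPM in Col0 (SD, n = 3), a log2 difference of -2.77 ± 0.23 (SE), or -2.58 relative (adjusted p = 7.48e-10), and SEP3 differed by -2.57 relative. GRP19 differed by -5.78 ± 0.68 (SE), or -5.59 relative (adjusted p = 2.60e-07), and CYP96A15 (AT1G57750), an alkane hydroxylase of wax synthesis, by -5.76 ± 0.54 (SE), or -5.57 relative (adjusted p = 4.78e-09). AT1G75945 and AT1G14250 were higher in pp7l by 4.09 and 3.81 relative.

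Of the floral organ markers at 9 D, 7 of 7 measured genes were lower (7 lower adjusted over the list alone). Their median was -1.78 relative (camera, adjusted p = 9.25e-11, and adjusted p = 0.148 with an estimated correlation). Of the wax and lipid transfer genes, 8 of 9 measured genes were lower (8 lower adjusted over the list alone). Their median was -1.83 relative (camera, adjusted p = 3.38e-07, and adjusted p = 0.253 with an estimated correlation), with CER1 at -2.13 relative. In anthocyanin synthesis, 12 of 13 measured genes were lower (12 lower adjusted over the list alone). Their median was -1.66 relative (camera, adjusted p = 8.63e-11, and adjusted p = 0.253 with an estimated correlation), with DFR at -2.07 relative. Mean DFR at 6, 9, 12 and 15 D was 97.8, 26.7, 123 and 69.3 TPM in pp7l (n = 3). In Col0 it was 6.65, 134, 114 and 8.98 TPM (n = 3, and n = 2 at 6 D). DFR was thus lower in pp7l at 9 D but not at those other days. TT4 and LDOX in pp7l were also lower at 9 D than at 6 D and 12 D. Among plastid-encoded transcripts, 13 of 71 measured loci were higher (18 higher adjusted over the list alone). Their median was 1.02 relative (camera, adjusted p = 2.10e-16, and adjusted p = 0.369 with an estimated correlation), and after median-of-ratios scaling 39 were higher and 0 lower. For pp7l versus Col0 at 9 D limma called 2746 genes, 573 higher and 2173 lower (194 and 1379 at least 2-fold), around a median gene at -0.19. After median-of-ratios scaling 1669 were higher and 2447 lower. The count was 7399 in a fit on these 6 libraries.

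At 12 D the dehydration and phosphatase transcripts were lower, and photosynthesis transcripts higher, in pp7l. RAB18 stood at 82.9 ± 45.5 TPM in pp7l and 2715 ± 646 TPM in Col0 (SD, n = 3), a log2 difference of -5.13 ± 0.53 (SE), or -4.94 relative (adjusted p = 9.97e-09), and HAI1 differed by -4.55 ± 0.34 (SE), or -4.37 relative (adjusted p = 3.23e-11). GER1 differed by 6.39 ± 0.34 (SE), or 6.58 relative (adjusted p = 6.83e-14) and PCC1 (AT3G22231), a protein regulated by the clock and by pathogens, by 5.93 ± 0.62 (SE), or 6.11 relative (adjusted p = 1.46e-08). GILT (AT4G12960), a thiol reductase, stood at 0.0531 ± 0.0920 TPM in pp7l and 229 ± 86.5 TPM in Col0 (SD, n = 3), and DELTA-VPE (AT3G20210), a vacuolar processing enzyme of the seed coat, was listed at 0 in pp7l and at 78.1 ± 25.5 TPM in Col0 (SD, n = 3).

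Of the ABA and dehydration markers at 12 D, 19 of 24 measured genes were lower and 2 higher (19 lower and 2 higher adjusted over the list alone). Their median was -2.37 relative (camera, adjusted p = 4.12e-07, and adjusted p = 0.433 with an estimated correlation). Of the clade A phosphatases, 9 of 9 measured genes were lower (9 lower adjusted over the list alone). Their median was -2.05 relative (camera, adjusted p = 7.60e-08, and adjusted p = 0.401 with an estimated correlation). Among photosynthesis genes, 17 of 20 measured light-harvesting genes were higher (17 higher adjusted over the list alone). Their median was 2.45 relative (camera, adjusted p = 9.62e-10, and adjusted p = 0.401 with an estimated correlation), and PSAN differed by 3.11 relative. In glucosinolate synthesis, 9 of 10 measured genes were higher (9 higher adjusted over the list alone). Their median was 2.22 relative (camera, adjusted p = 2.50e-06, and adjusted p = 0.401 with an estimated correlation). Of the floral organ markers, 6 of 7 measured genes were lower (7 lower adjusted over the list alone). Their median was -1.53 relative (camera, adjusted p = 5.57e-04, and adjusted p = 0.401 with an estimated correlation). PI stood at 0.456 ± 0.150 TPM in pp7l and 4.32 ± 0.807 TPM in Col0 (SD, n = 3) and SEP3 at 0.594 ± 0.166 TPM in pp7l and 7.73 ± 0.940 TPM in Col0 (SD, n = 3). Among plastid-encoded transcripts, 58 of 71 measured loci were higher (62 higher adjusted over the list alone). Their median was 1.90 relative (camera, adjusted p = 7.72e-16, and adjusted p = 0.401 with an estimated correlation), and after median-of-ratios scaling 59 were higher and 0 lower. In Col0 12 D replicate 3, rRNA loci held 25.0% and plastid loci 31.5% of TPM. For pp7l versus Col0 at 12 D limma called 7979 genes, 3219 higher and 4760 lower (1834 and 2881 at least 2-fold), around a median gene at -0.19. After median-of-ratios scaling 4541 were higher and 4624 lower.

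At 15 D photosynthesis transcripts were higher in pp7l than in Col0, and seed storage transcripts were lower. The libraries differed in nuclear rRNA, which held 0.110% to 61.2% of TPM in Col0 and at most 0.110% in pp7l. ESM1 (AT3G14210), a modifier of glucosinolate breakdown, stood at 419 ± 55.9 TPM in pp7l and 0.0423 ± 0.0325 TPM in Col0 (SD, n = 3), a log2 difference of 8.65 ± 0.37 (SE), or 7.38 relative (adjusted p = 1.98e-15). BGLU18 (AT1G52400), a glucosidase that releases ABA, LOX2 and PRXR1 (AT4G21960), a peroxidase, differed by 6.33, 5.59 and 5.46 relative, and ATMG01190 was listed at 0 in Col0 and at 122 ± 5.24 TPM in pp7l (SD, n = 3). SESA3 and AT5G38160 were listed at 0 in pp7l and stood at 49.1 ± 37.3 and 61.0 ± 30.9 TPM in Col0 (SD, n = 3). CRA1, AT1G62060, the pseudogene AT2G35743 and the rRNA locus AT2G01020 differed by -6.36, -7.16, -7.35 and -10.08 relative.

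Of the seed storage genes, 9 of 9 measured genes were lower (9 lower adjusted over the list alone). Their median was -5.87 relative (camera, adjusted p = 8.59e-39, and adjusted p = 0.00109 with an estimated correlation), so the call held with both. Their fitted changes depend on the pseudocount, since they are near 0 in pp7l. Of the clade A phosphatases, 5 of 9 measured genes were lower (5 lower adjusted over the list alone). Their median was -1.92 relative (camera, adjusted p = 1.37e-08, and adjusted p = 0.375 with an estimated correlation), with HAI1 at -4.11 relative. Counts of higher members stand against 14532 of all 18757 tested genes called higher in pp7l (5796 after median-of-ratios scaling). Among photosynthesis genes, 20 of 20 measured light-harvesting genes were higher (20 higher adjusted over the list alone). Their median was 3.75 relative (camera, adjusted p = 8.79e-07, and adjusted p = 0.686 with an estimated correlation), with PSAN at 4.17 and RBCS3B at 3.19 relative. Among plastid-encoded transcripts, 67 of 71 measured loci were higher (67 higher adjusted over the list alone). Their median was 2.95 relative (camera, adjusted p = 4.42e-08, and adjusted p = 0.686 with an estimated correlation), and after median-of-ratios scaling 53 were higher and 6 lower. The ABA and dehydration markers turned with the scaling, with 10 higher and 5 lower as deposited (9 and 5 adjusted over the list alone) against 3 and 17 after median-of-ratios scaling. Their median was 0.44 and their mean 0.64 as deposited but -0.82 relative to the median gene, and camera, which ranks against the other genes, gave lower (adjusted p = 3.68e-04; adjusted p = 0.686 with an estimated correlation).

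For pp7l versus Col0 at 15 D limma called 15368 genes, 14532 higher and 836 lower (11542 and 501 at least 2-fold), around a median gene at 1.26. Median-of-ratios scaling gave 5796 higher and 6143 lower, with 6632 genes called in the same and 2598 in the opposite direction.

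**Figure D3:**
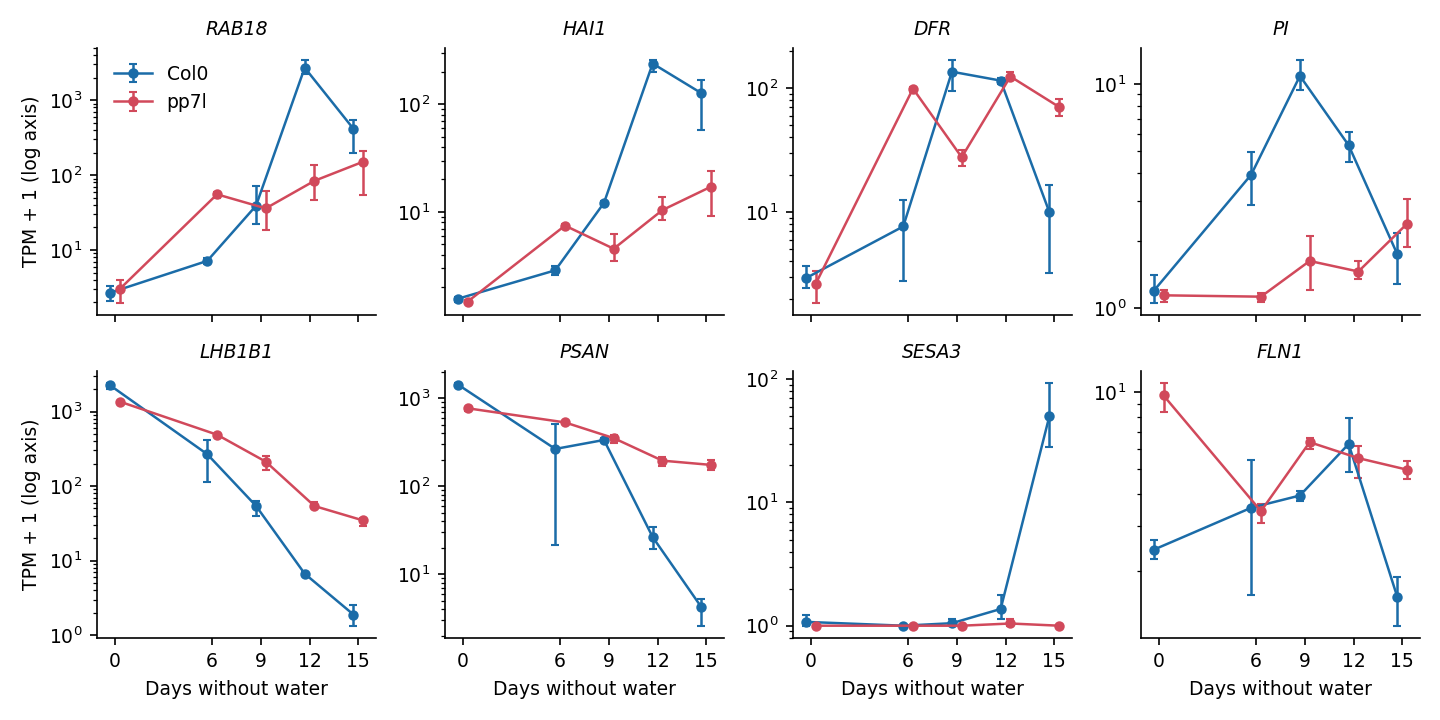
TPM + 1 on a log axis of 8 genes against days without water in Col0 (blue) and pp7l (red); points are group means and bars run from the lowest to the highest library (n = 3, and n = 2 for Col0 at 6 D). RAB18 reached 2715 TPM in Col0 and 82.9 TPM in pp7l at 12 D.

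Whether pp7l and Col0 changed differently from 0 D was tested as the difference of their changes. Without watered plants at the later days, this difference holds both the lack of water and age, flowering included. A different answer to the lack of water cannot be told apart from a different course of ageing or flowering. In the change of pp7l minus that of Col0 by 15 D, 20 of 20 measured light-harvesting genes were higher (20 higher adjusted over the list alone). Their median was 4.44 relative (camera, adjusted p = 1.38e-13, and adjusted p = 0.48 with an estimated correlation). At 15 D, 9673 ± 3001 loci reached 1 TPM in Col0 and 16650 ± 221 in pp7l (SD, n = 3). Nuclear rRNA loci held 0.110% to 61.2% of TPM in these Col0 libraries, and an effect of RNA quality was not tested. Of the seed storage genes, 9 of 9 measured genes were lower (9 lower adjusted over the list alone). Their median was -5.49 relative (camera, adjusted p = 2.63e-38, and adjusted p = 0.00117 with an estimated correlation), so the call held with both. ESM1 went from 142 ± 60.2 to 0.0423 ± 0.0325 TPM in Col0 and from 272 ± 18.9 to 419 ± 55.9 TPM in pp7l (SD, n = 3). The genotype difference in the change from 0 D to 15 D was called by limma for 10195 genes, 9559 higher and 636 lower (7656 and 508 at least 2-fold), around a median gene at 0.88. After median-of-ratios scaling 4406 were higher and 5138 lower, with 52 called in opposite directions.

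AT2G45180 went from 565 ± 28.5 to 4.75 ± 4.96 TPM in Col0 and from 394 ± 12.2 to 277 ± 65.9 TPM in pp7l by 12 D (SD, n = 3). PER64 (AT5G42180), a peroxidase, went from 0.0469 ± 0.0813 to 82.5 ± 10.4 TPM in Col0 and from 0.611 ± 0.400 to 0.572 ± 0.311 TPM in pp7l by 9 D (SD, n = 3). GRP7 (AT2G21660), an RNA-binding protein, went from 11.9 ± 1.19 TPM (SD, n = 3) to 343 ± 347 TPM (SD, n = 2) in Col0 and from 42.4 ± 2.12 to 30.0 ± 5.47 TPM in pp7l by 6 D (SD, n = 3), a difference not called with array weights. At 12 D the difference in change was called for 7808 genes, 1691 higher and 6117 lower (1349 and 5055 at least 2-fold), around a median gene at -0.52. After median-of-ratios scaling 4248 were higher and 4409 lower.

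The genotype difference in the change from 0 D to 9 D was called by limma for 2917 genes, 96 higher and 2821 lower (68 and 2387 at least 2-fold), around a median gene at -0.51, and for 984 higher and 1749 lower after median-of-ratios scaling. That count was 1460 without Col0 0 D replicate 3, 1913 without Col0 9 D replicate 1 and 4429 without Col0 15 D replicate 3. It was 1692 without pp7l 0 D replicate 3, and 1879 and 1889 without pp7l 9 D replicates 1 and 2.

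The genotype difference in the change from 0 D to 6 D was called for 679 genes, 360 higher and 319 lower (347 and 298 at least 2-fold), around a median gene at 0.15, and for 3095 higher and 2654 lower after median-of-ratios scaling. That count was 437 without Col0 0 D replicate 1, 344 without Col0 0 D replicate 3, 1366 without Col0 6 D replicate 1, 8401 without Col0 6 D replicate 3, 1456 without Col0 15 D replicate 3, 400 without pp7l 0 D replicate 1, 418 without pp7l 0 D replicate 2, 376 without pp7l 0 D replicate 3, 386 without pp7l 6 D replicate 1, 372 without pp7l 6 D replicate 2 and 411 without pp7l 6 D replicate 3, with a lone Col0 6 D library assumed to vary like the other groups. With limma's array weights it was 0 (804 at an unadjusted p under 0.05).

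Moderated F-tests of limma over all days called 18156 genes for any day against 0 D in Col0 and 8658 in pp7l, 17658 for pp7l against Col0 at any day and 17135 for the interaction of genotype and day. After median-of-ratios scaling these counts were 17268, 8562, 16078 and 13942. Across genes, the rescaled changes of both genotypes correlated with r = 0.46 at 6 D, 0.69 at 9 D, 0.67 at 12 D and 0.69 at 15 D; genes are not independent replicates. Between days, the highest r of pp7l at 6 D and 9 D was with Col0 at 9 D (0.65 and 0.69), and that of pp7l at 12 D and 15 D was with Col0 at 12 D (0.67 and 0.74), the former also 0.67 with Col0 at 9 D. The SD of the same-day changes over genes was 1.67 in Col0 and 0.82 in pp7l at 15 D.

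**Figure D4:**
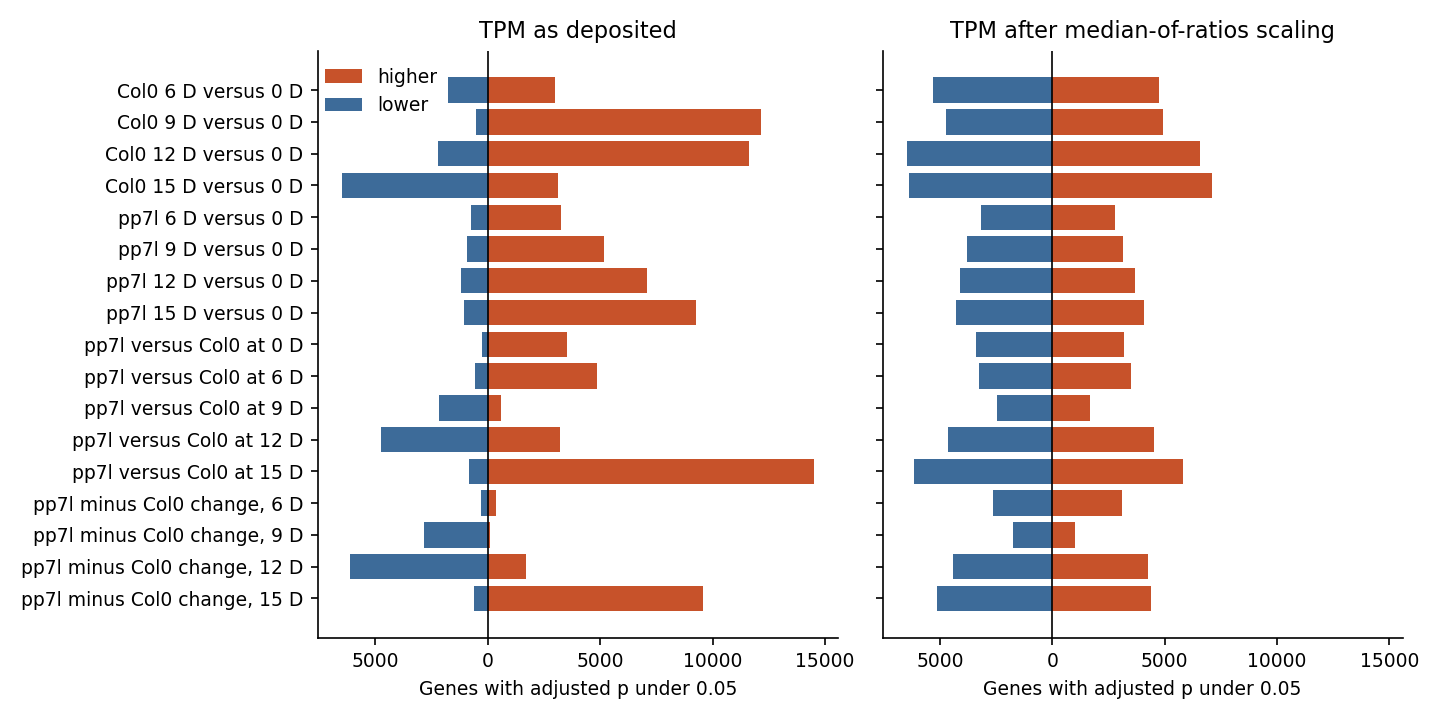
Number of genes with an adjusted p under 0.05, higher (orange, right) and lower (blue, left), in each comparison, as deposited and after median-of-ratios scaling. In pp7l versus Col0 at 15 D, 14532 genes were higher as deposited and 5796 after scaling.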

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

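The test of the next most abundant loci, the tests of 1 library and of scaling for the seed storage genes, and the comparison of Col0 6 D replicate 1 with other groups were chosen after the result was seen.

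The changes of pp7l and Col0 from 0 D differed in limma's test of that difference for 679 genes by 6 D, 2917 by 9 D, 7808 by 12 D and 10195 by 15 D, and for 17135 genes over all days. By 6 D the difference of changes (pp7l minus Col0, log2) was 5.08 for AT2G37870, 4.40 for AT3G02480, -4.73 for GRP7 and -9.06 for the noncoding locus AT3G41761. AT3G41761 lost its call in 8 of 38 alternatives (adjusted p up to 1, with array weights) and stood at -4.95 without Col0 6 D replicate 1, and none of the 4 genes named for 6 D was called with array weights. By 9 D it was 3.15 for AT1G66100, 2.89 for AT1G14250, -6.34 for PER64 and -5.78 for GRP19, which was listed at 0 in both groups of 0 D. By 12 D it was 6.41 for AT2G45180, 6.00 for PCC1, -7.70 for GILT, listed at 0 in both groups of 0 D, and -6.32 for the small nucleolar RNA locus SNOR77 (AT5G10572). SNOR77 lost its call in 13 of 38 alternatives (adjusted p from 0.00341 to 0.172, the latter with -4.10 without pp7l 12 D replicate 3). By 15 D it was 7.61 for ESM1, 7.22 for AT2G45180, -6.49 for the pseudogene AT2G35743 and -5.89 for AT1G62060, listed at 0 in both groups of 0 D. Fitted values of genes listed at 0 depend on the pseudocount.

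The 100 splits drawn for each difference of changes and each F-test include the real one. For the difference by 9 D, 5 of 100 gave as many genes (real 2917, highest other 12370), so chance is not excluded. By 12 D, 3 of 100 did (7808, highest other 12938), and by 15 D 1 of 100 (10195, highest other 9698). These splits shuffle the libraries over all compared groups, so differences between days or genotypes can pass into a difference of changes. They cannot decide on chance for a difference of changes, and no conclusion is drawn from them. By 9 D the highest other was several times the real count and by 12 D it was also above it. Which differences between the shuffled libraries gave these counts was not tested. For any day versus 0 D, 1 of 100 gave as many in Col0 (18156, highest other 16575) and 1 of 100 in pp7l (8658, highest other 4054). It was also 1 of 100 for pp7l versus Col0 at any day (17658, highest other 827) and for the interaction (17135, highest other 4819). The splits for both also shuffle the days, so they test neither genotype nor interaction alone. Within a genotype no other split gave as many genes for any day versus 0 D. That argues against chance there, without adjustment over the tests. Comparisons with Col0 at 6 D, a group of 2, had no count of splits.

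Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05, and in each of them 1 split, the real one, gave as many genes. The real count and the highest other were 12692 and 0 in Col0 at 9 D, 13837 and 1 at 12 D, and 9630 and 1 at 15 D. In pp7l they were 4010 and 1 at 6 D, 6139 and 0 at 9 D, 8277 and 1 at 12 D, and 10325 and 8 at 15 D. For pp7l versus Col0 they were 3794 and 0 at 0 D, 2746 and 0 at 9 D, 7979 and 1 at 12 D, and 15368 and 97 at 15 D. In pp7l versus Col0 at 15 D, all pairs of libraries with the same replicate number correlated by more than 0.1 after removal of group means. The labels do not say what these numbers share. There the highest other was 16 among the 4 splits that part all pairs, and the 97 came from a split that does not.

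At 15 D, 14532 of 15368 called genes were higher in pp7l than in Col0 in deposited TPM, around a median log2 difference of 1.26. With organellar loci, rRNA loci and AT1G15405 left out (241 loci) the median was 1.05 (11647 higher and 2077 lower), above the bound of 0.5 times the deposited one that had been set against a few loci taking most of the TPM. That bound was set wrongly, because the 10 most abundant of the remaining loci, among them RR3 with 9.81% in Col0 and 1.38% in pp7l, still held 27.7%, 37.0% and 43.1% of the remaining TPM in the Col0 libraries and 11.2% to 12.1% in those of pp7l. With 17 such loci left out too the median was 0.681 (9429 higher and 3144 lower) and the closest pair of libraries differed by 0.546, after 0.766 in the first step. A few loci taking most of the TPM may therefore account for much of the pattern and cannot be told apart from a wider difference between the genotypes, which stays open as untested, and so does RNA quality in Col0 at 15 D, where rRNA loci held 0.110% to 61.2% of TPM.

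The seed storage genes rose in Col0 at 15 D. A single library is argued against, since 3 of 3 Col0 15 D libraries lay above all libraries of the other groups in the median of these genes, and so is scaling, which moves all genes of a library alike, since the median gene changed by -0.23 and the median of the list by 4.60 (log2). Seed-bearing tissue is a candidate source, and 9 other genes of seeds and ovules changed by a median of 0.45 (SD over genes 0.53), 5 of them reaching 1 TPM in some library. TT10 stood at 2.36 ± 1.13 and FAE1 at 0.729 ± 0.294 TPM in Col0 at 15 D (SD, n = 3), and BAN at 5.21, STK at 3.24 and LEC1 at 1.12 TPM in Col0 at 12 D, while DELTA-VPE, a seed coat gene outside that list, stood at 78.1 ± 25.5 TPM at 12 D and 10.6 ± 6.05 TPM at 15 D. The levels of the 9 genes are too near the floor to decide, and a single other gene decides nothing, although that median met the bound of 0.5 set against this source, so seed-bearing tissue and a response of other tissues to drought or age cannot be told apart.

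Col0 6 D replicate 1 stood apart, with a rank correlation across genes of 0.738 with its group mate. An exchange with another group of this study is argued against as the whole cause, since its highest correlation with a library of another group was 0.720, below the lowest within the other groups (0.928); an exchange beside low depth, or with a sample from outside, stays open. It had 15705 loci at 0, and 0 of the 213 genes at 20 TPM or more in all other libraries were among them, but that count was 0 for every library and decides nothing about low depth. Genes at 5 TPM or more in all others were listed at 0 in 6 cases, and no other library had such a gene. Low depth stays open, since no read numbers are given, and no biological explanation was tested.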

How the results depend on the processing

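The alternative that leaves out both libraries that stand apart (Col0 6 D replicate 1 and Col0 15 D replicate 3) was chosen after seeing the data, and the others before the data were examined. Among named genes, 180 of 199 kept their call and direction in every alternative run, with adjusted p up to 0.0499, and 19 lost the call in some, most of them genes of 6 D. Among the called list tests, 58 of 61 did so over all alternatives but the estimated correlation, with adjusted p up to 0.0263, and 59 of 61 lost the call with that correlation. The lists that lost it otherwise were cell division in pp7l versus Col0 at 0 D (6 of 36, adjusted p up to 0.260), editing factors in pp7l versus Col0 at 0 D (1 of 36, up to 0.134) and ABA markers in Col0 at 9 D (2 of 36, up to 0.0896). With nuclear loci alone, 57 of all 62 list tests, 1 of them not called, could be run, since the plastid lists drop out. With no filter and with the replicate block all 21 counts of called genes stayed within 1.5 times. With the replicate block the plastid shares gave permutation p = 0.00047 over days in Col0 and 0.0461 between genotypes. Without read counts, depth limits what can be said of genes near 0 and of libraries with many loci at 0. The shares of protein-coding organellar loci alone were not run.

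Counts of called genes that moved by more than 1.5 times follow, with pp7l versus Col0 written as genotypes. With a pseudocount of 0.1 they were 2673 for pp7l 6 D, 1769 for genotypes at 9 D and 429 for difference of changes to 6 D. With a minimum of 5 TPM in 3 libraries, where fewer genes are tested, they were 7776 for Col0 9 D, 8839 for Col0 12 D, 2463 for pp7l 6 D, 3660 for pp7l 9 D, 5156 for pp7l 12 D, 6483 for pp7l 15 D, 2489 for genotypes at 0 D, 1416 for genotypes at 9 D, 5120 for genotypes at 12 D, 9642 for genotypes at 15 D, 1771 for difference of changes to 9 D, 6621 for difference of changes to 15 D, 11411 for any day in Col0, 5251 for any day in pp7l, 11082 for genotypes at any day and 10969 for interaction. With median-of-ratios scaling they were 10049 for Col0 6 D, 6598 for genotypes at 0 D and 5749 for difference of changes to 6 D. With nuclear loci alone in the total they were 8363 for Col0 6 D, 1699 for difference of changes to 6 D and 1602 for difference of changes to 9 D. In limma fits on the compared groups alone, where the spread of the other groups does not enter, they were 0 for Col0 6 D (2602 at an unadjusted p under 0.05), 9655 for pp7l 6 D, 10662 for pp7l 9 D, 7634 for genotypes at 0 D, 0 for genotypes at 6 D (2119 at an unadjusted p under 0.05), 7399 for genotypes at 9 D, 201 for difference of changes to 6 D, 8990 for difference of changes to 9 D and 14352 for any day in pp7l. With limma's array weights they were 2 for Col0 6 D, 11512 for pp7l 6 D, 12549 for pp7l 9 D, 13662 for pp7l 12 D, 7201 for genotypes at 0 D, 0 for genotypes at 6 D (883 at an unadjusted p under 0.05), 9739 for genotypes at 9 D, 12225 for genotypes at 12 D, 0 for difference of changes to 6 D (804 at an unadjusted p under 0.05), 9035 for difference of changes to 9 D and 16330 for any day in pp7l. Without both libraries that stand apart they were 10187 for Col0 6 D, 8685 for pp7l 6 D, 10520 for pp7l 9 D, 8444 for genotypes at 0 D, 1543 for genotypes at 6 D, 7009 for genotypes at 9 D, 4160 for difference of changes to 6 D, 8590 for difference of changes to 9 D, 11774 for difference of changes to 12 D and 14207 for any day in pp7l. Apart from fewer genes or samples, the cause was not tested.

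Leaving out each library in turn gave 3202 to 8193 for Col0 6 D, 11458 to 14126 for Col0 9 D, 12895 to 14870 for Col0 12 D, 8437 to 11109 for Col0 15 D, 2205 to 6548 for pp7l 6 D, 3982 to 8627 for pp7l 9 D, 6054 to 10582 for pp7l 12 D, 8473 to 12328 for pp7l 15 D, 1369 to 6318 for genotypes at 0 D. It also gave 727 to 13033 for genotypes at 6 D, 1887 to 4480 for genotypes at 9 D, 6391 to 9997 for genotypes at 12 D, 14111 to 15946 for genotypes at 15 D, 344 to 8401 for difference of changes to 6 D, 1460 to 5828 for difference of changes to 9 D, 6461 to 10158 for difference of changes to 12 D, 8344 to 12159 for difference of changes to 15 D, 18026 to 18313 for any day in Col0, 6425 to 12041 for any day in pp7l, 17343 to 18238 for genotypes at any day, 16566 to 17903 for interaction. Where a single Col0 6 D library was left, it is assumed to vary like the other groups. The permutation p of the plastid share ranged from 0.00021 to 0.00224 over days in Col0, from 1e-05 to 6e-05 in pp7l and from 0.00026 to 0.0721 between genotypes. That of the mitochondrial share ranged from 0.00539 to 0.0585 in Col0, from 1e-05 to 3e-05 in pp7l and from 0.223 to 0.983 between genotypes. The mitochondrial share of TPM in pp7l versus Col0 turned its sign in the permutation test as a log2 ratio to nuclear TPM (p = 0.255, difference 0.26), without Col0 6 D replicate 3 (p = 0.983, 0.00272) and without Col0 15 D replicate 1 (p = 0.908, 0.0164), and the cause was not tested.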

Other observations

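In Col0 at 15 D, 6 of 9 measured heat shock genes were higher (6 higher adjusted over the list alone). Their median was 2.08 relative (camera, adjusted p = 6.03e-04, and adjusted p = 0.281 with an estimated correlation). In the mitochondrial dysfunction response, 7 of 10 measured genes were higher and 2 lower (8 higher and 2 lower adjusted over the list alone). Their median was 1.54 relative (camera, adjusted p = 0.00163, and adjusted p = 0.447 with an estimated correlation). AOX1D (AT1G32350) and AOX1A (AT3G22370), alternative oxidases of the mitochondrion, changed by 5.31 ± 0.59 (SE), or 5.54 relative (adjusted p = 2.04e-08) and 2.62 ± 0.38 (SE), or 2.85 relative (adjusted p = 1.73e-06). In pp7l at 15 D AOX1D changed by 4.48 ± 0.59 (SE), or 3.87 relative (adjusted p = 1.70e-06). At 9 D in Col0, 6 of 7 measured vascular genes were higher (6 higher adjusted over the list alone). Their median was 1.31 relative (camera, adjusted p = 0.00185, and adjusted p = 0.438 with an estimated correlation). IRX1 (AT4G18780) and IRX3 (AT5G17420), cellulose synthases of secondary walls, stood at 2.98 and 2.77 relative.

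Before drought, of the cell division genes, 7 of 9 measured genes were higher (8 higher adjusted over the list alone). Their median was 0.44 relative (camera, adjusted p = 0.0267, and adjusted p = 0.674 with an estimated correlation), and after median-of-ratios scaling 3 were higher and 1 lower. The call of this list was also lost in some of the other alternatives, as given above. CYC1BAT (AT5G06150), a mitotic cyclin, stood at 0.74 relative.

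Loci that part the genotypes on all days were looked for after seeing the data. In 102 loci every pp7l library was above every Col0 library, 35 of them also after median-of-ratios scaling, and in 6 every pp7l library was below, all 6 also after scaling. Of the 102, 15 were plastid loci, 0 of them also after scaling, and 10 were pseudogenes. On the scale of log2(TPM + 1) the widest gaps were 10.3 to 30.8 TPM in pp7l and 0 to 1.39 TPM in Col0 for AT1G75945, 3.05 to 8.10 TPM in pp7l and 0 to 0.0929 TPM in Col0 for AT3G29639 and 3.62 to 7.87 TPM in pp7l and 0 to 0.364 TPM in Col0 for MRD1 (AT1G53480). QQS (AT3G30720), a gene of carbon and nitrogen allocation, stood at 14.3 to 41.7 TPM in pp7l and 0.264 to 6.46 TPM in Col0. AT1G53530, AT4G17180 and SR (AT4G11640) were listed at 0 in all pp7l libraries, and MKK3 (AT5G40440), a MAP kinase kinase, stood at 0 to 0.149 TPM in pp7l and 0.494 to 7.03 TPM in Col0. The other loci lower in pp7l were FAP3 (AT1G53520) and AT3G10970. Group means of the root marker PYK10 were 26.0 to 68.2 TPM in pp7l and 0.0446 to 13.6 TPM in Col0. Unequal root tissue between genotypes was not tested.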
